A study of Homo sapiens with 4 samples.

How the data were processed

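RNA bound to HuR in THP-1 macrophages was measured by FLASH in 4 libraries: 2 of wild type cells, 1 of cells with circARCN1 knockdown and 1 of cells with circARCN1 overexpression. The modified lines were made with lentivirus and selected with puromycin, per the labels' protocols. The labels do not say that the wild type replicates came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

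The authors deposited a table of whole-number counts per gene, and its values were used as deposited. Reads were handled with Trimmomatic 0.39 and HISAT2 2.2.1 on the genome build hg38, per the submitters' processing notes. The counting tool, its annotation, and how strand, duplicates and reads with several matches were handled are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene could not be told apart. The table held 62754 genes, of which 42361 carried a symbol, and 16686 had at least 1 count. Of the identifiers, 58261 (92.8%) were found in GENCODE 29, which gave gene classes and GRCh38 coordinates and may differ from the annotation behind the counts.

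Library totals ran from 612453 to 3639710 counts, so the values of wild type replicate 2 carried the largest counting error. More genes had exactly 4 counts than 3 or 5 in every library, most clearly in wild type replicate 2, with 1065 genes at 4, 593 at 3 and 446 at 5. The numbers were 494, 441 and 297 in wild type replicate 1, 596, 420 and 290 in the knockdown, and 473, 376 and 238 in the overexpression. Counts may thus not stand for separate fragments. Shares of counts were given with 95% exact Clopper-Pearson intervals, ratios between libraries with 95% exact binomial intervals, and folds against a group at 0 with a floor of 3 counts over that group, except at USP31, where the exact interval of the ratio was given. All of these covered counting error only. They take each count as a separate fragment, and are too narrow where 1 fragment added several counts.

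Genes were filtered with filterByExpr, which left 9738 and could admit a gene through 1 library alone. Libraries were scaled with TMM (factors 1.27, 0.718, 1.05 and 1.04 for wild type replicates 1 and 2, the knockdown and the overexpression). The main test was edgeR's quasi-likelihood F-test (version 4.0.16, R 4.3.3) with group as the only term, at a Benjamini-Hochberg adjusted p below 0.05, for knockdown minus wild type, overexpression minus wild type, and overexpression minus knockdown. The fit had 1 residual degree of freedom, between the wild type replicates, and each lone library was assumed to vary like that pair. The common dispersion was 2.80, a biological coefficient of variation of 1.67. Log2 CPM values had a prior count of 2. Genes at least 2-fold beyond both wild type libraries were counted without a test.

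The procedure was tested on simulated data for knockdown against wild type, drawn for 9738 genes with 200 changed. At the estimated dispersion, 0 of the 200 were recovered among 8569 genes that passed the filter, with 0 false calls, at folds of 4, 16 and 64. At a dispersion of 0.1, 43.3% of the genes changed 4-fold and 100% of those changed 16-fold or 64-fold were recovered among 9133 genes, with 8 false calls.

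Before the data were examined, 22 gene lists were fixed, with members chosen from general knowledge or by symbol. They covered HuR targets, inflammatory mediators, the NF-kB pathway, deubiquitinases, lipid and cholesterol handling, macrophage markers, monocyte and cell cycle markers, interferon response, p53 and stress response, immediate early genes and RNA-binding proteins of decay and splicing. They also covered nuclear long noncoding RNAs (a list name, as location was not checked), lysosome and phagocytosis, the coatomer, and cytoskeleton and adhesion. Ribosomal proteins, mitochondrial transcripts, histones and small noncoding RNAs had lists too. Marker lists covered T and B cells, erythroid cells and platelets, and epithelial cells and fibroblasts. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 21 lists within each contrast; T and B cell markers had 1 tested member and were not tested. Each list's median was also placed among 10000 random lists matched on mean abundance, with ties counted as below. Medians were recomputed with members at 0 in a group set to their bounds.

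Genes named in the text were chosen by a rule fixed at the same time: USP31, ARCN1 and ELAVL1, the 20 protein-coding genes with the highest mean wild type CPM, and for each modified line the 8 higher and 8 lower protein-coding genes with a value outside the wild type range and at least 50 counts in the higher group. Passing genes came first, ranked by fold change, and the rest were filled by smallest p. Up to 4 members of each list with the smallest p in a contrast could be named. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 50 counts in 2 libraries, protein-coding genes alone, a dispersion from all libraries as one group, only the libraries compared, prior counts of 0.5 and 5, and each wild type replicate alone. Sequence of 3' untranslated regions came from the GENCODE 29 transcripts, taking the longest region of at least 50 bases per gene. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. circARCN1 itself was not counted here, and no peak or crosslink position was analysed.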

Results

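RNA bound to HuR was sequenced from THP-1 macrophages in 4 libraries. HuR, the product of ELAVL1, is an RNA-binding protein known to bind U-rich and AU-rich stretches of messenger RNAs, often in 3' untranslated regions. THP-1 is a human leukaemia line of monocytic cells, which were turned into macrophage-like cells with the phorbol ester PMA at 100 ng/mL for 48 h. In FLASH, RNA crosslinked to a protein is purified with an antibody, ligated to adapters and sequenced. Wild type cells gave 2 libraries, cells with knockdown of the circular RNA circARCN1 gave 1, and cells with its overexpression gave 1. The counts assigned to genes totalled 3639710 in wild type replicate 1, 612453 in wild type replicate 2, 3072535 in the knockdown and 3349690 in the overexpression. At least 10 counts fell on 6418, 1545, 5371 and 4557 genes in these libraries, in that order. Counts were not corrected for the level of each transcript, since no input or RNA-seq library was analysed here, and the knockdown and overexpression values had no replicate check. Intervals and floors quoted here covered counting error only, and took each count as a separate fragment. Intervals are too narrow where 1 fragment added several counts.

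Which RNAs were recovered with HuR in wild type macrophages was the first question. ELAVL1, the transcript of HuR itself, ranked first among protein-coding genes in both libraries, at 7660 ± 2149 CPM (counts scaled to equal library totals; SD, n = 2). ACTB, which encodes beta-actin and is a known HuR target, followed at 4387 ± 3132 CPM (SD, n = 2). Among ribosomal protein and translation factor genes, RPS15 reached 3913 ± 4681 CPM, RPL29 3910 ± 3561, EIF3I 3139 ± 3837 and EEF1A1 2809 ± 913 (SD, n = 2 for each), and 6 of the 20 most abundant genes encoded ribosomal proteins. RPS15 ranked 68 and EIF3I 131 in replicate 1, against 2 and 5 in the shallower replicate 2. The 20 also held DDX6, an RNA helicase of mRNA decay, at 2637 ± 3170 CPM, SND1 at 2658 ± 3445, the histone gene H4C3 at 2674 ± 2332 and the chromatin regulator MSL2 at 2859 ± 3946 (SD, n = 2 for each). RPL26, RPL15, RPL27A, RPS7, ACTR2, KIF5B, GINS3, PPIL1, BIRC6 and LPGAT1 completed the 20, with means from 2161 to 2484 CPM. Of these 20 genes, 17 were at least 2-fold higher in replicate 2 than in replicate 1, and GINS3 had 0 counts in replicate 1 against 2822 in replicate 2. Replicate 1 alone placed 6 of the 20 among its own top 20, and replicate 2 alone placed 17. Reads of ACTB, EEF1A1 and the ribosomal protein genes could be shared with processed pseudogene copies, so their counts are uncertain.

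ELAVL1 lies on chromosome 19 from 7958579 to 8005659 on the minus strand (GRCh38 coordinates from GENCODE 29), and its identifier is ENSG00000066044. It held 22348 and 5622 counts in wild type replicates 1 and 2, 24304 in the knockdown and 20647 in the overexpression. The 38 listed HuR targets together took 1.13% and 1.67% of the wild type counts, 1.25% of the knockdown counts and 1.01% of the overexpression counts. ELAVL1 and ACTB, both members, made up most of this in every library. They held 22348 and 7908 of 41126 list counts in wild type replicate 1, and 5622 and 4043 of 10203 in replicate 2. In the knockdown they held 24304 and 2460 of 38386, and in the overexpression 20647 and 3828 of 33679. Transcripts of inflammatory mediators were scarce, with 31 genes sharing 50 and 33 counts in wild type replicates 1 and 2, 110 in the knockdown and 46 in the overexpression. Macrophage markers were scarce as well, at 48, 8, 261 and 473 counts over 25 genes in the same order. In the overexpression 425 of these counts fell on MERTK, which was chosen after its values were seen and had 0, 1 and 0 counts in the other libraries, and the rest of the list held 48. T and B cell markers had 46, 40, 19 and 27 counts over 16 genes.

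By RNA class, nuclear protein-coding genes took 52.6% of the counts in wild type replicate 1 (95% exact Clopper-Pearson interval 52.5 to 52.6), 45.3% in replicate 2 (45.2 to 45.4), 48.8% in the knockdown (48.7 to 48.9) and 45.5% in the overexpression (45.4 to 45.6). The ribosomal RNAs of mitochondria took 21.0% (21.0 to 21.0), 24.5% (24.4 to 24.6), 20.1% (20.1 to 20.2) and 25.5% (25.4 to 25.5). Nuclear ribosomal RNA and rDNA loci took 10.9%, 13.0%, 15.8% and 14.7%, and long noncoding RNAs 4.82%, 2.64%, 6.45% and 5.26%. Mitochondrial RNAs other than rRNA took 5.04% (5.02 to 5.06) and 4.87% (4.82 to 4.93) in the wild type libraries, 2.76% (2.74 to 2.78) in the knockdown and 2.50% (2.48 to 2.52) in the overexpression. Pseudogenes took 1.99%, 2.77%, 1.67% and 1.64%. Both modified lines lay below both wild type libraries in these last classes and above both in nuclear ribosomal RNA and in long noncoding RNAs. With 1 library per modified line no class was tested.

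**Figure D1:**
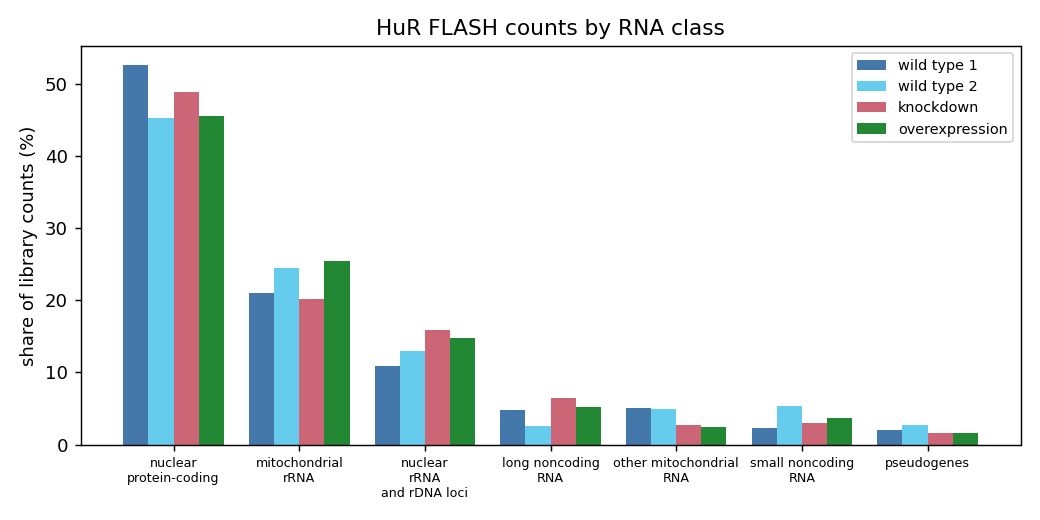
Share of each library's counts (%, vertical axis) by RNA class (horizontal axis), with 1 bar per library: wild type 1, wild type 2, knockdown and overexpression. Mitochondrial RNA other than rRNA took 5.04% and 4.87% of counts in the wild type libraries, 2.76% in the knockdown and 2.50% in the overexpression.

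Counts of single genes differed widely between the wild type replicates. Of 9738 genes tested, 7048 (72.4%) differed at least 2-fold between them after TMM scaling, and the Pearson correlation of log2 CPM across genes was 0.21 (Spearman 0.17). Across genes, which are not independent replicates, the 5 other pairs of libraries correlated at 0.17 to 0.23. DDX6 had 1442 counts in replicate 1 and 2988 in the shallower replicate 2, whereas ARCN1 had 658 and 13. The median difference of replicate 2 from replicate 1 was -1.56 log2 units with TMM scaling and -0.17 with upper-quartile scaling.

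**Figure D2:**
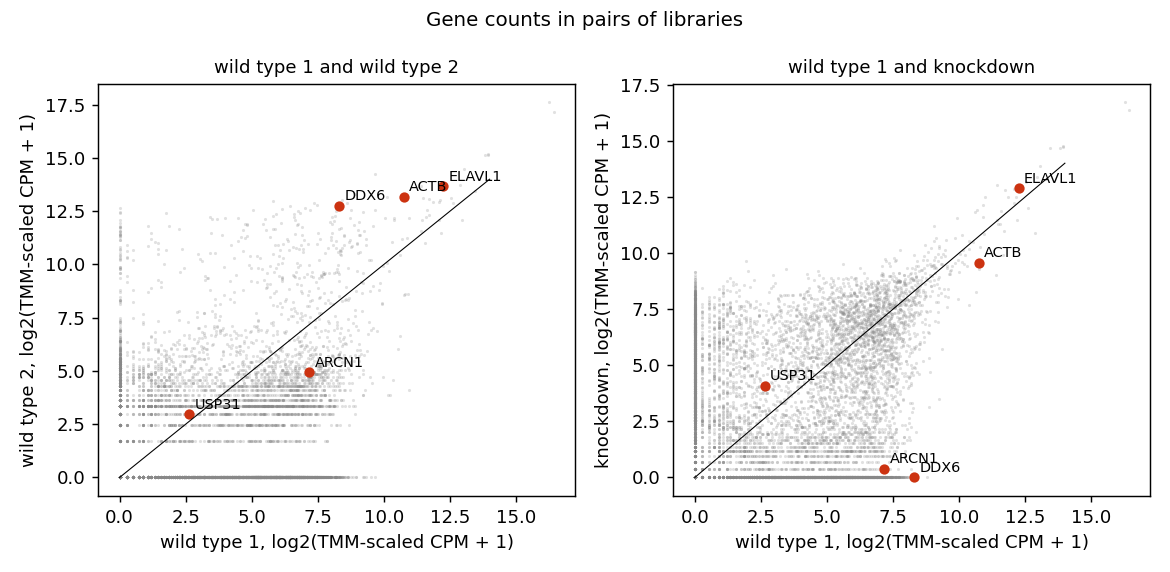
TMM-scaled CPM of each tested gene on a log2(CPM + 1) scale in wild type 1 (horizontal axes) against wild type 2 (left) or the knockdown (right); each grey point is a gene, red points are named genes and the line marks equality. ARCN1 had 658 counts in wild type 1, 13 in wild type 2 and 1 in the knockdown, and DDX6 had 1442, 2988 and 0.

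Knockdown and overexpression of circARCN1 were then examined at ARCN1, the gene after which the circular RNA is named. ARCN1 encodes the delta subunit of the coatomer, the coat of vesicles that return proteins to the endoplasmic reticulum. Counts of the gene were not counts of circARCN1, which was not measured separately here. ARCN1 (ENSG00000095139; chromosome 11, 118572390 to 118603033, plus strand) had 658 and 13 counts in the wild type replicates, 1 in the knockdown and 3057 in the overexpression. These were 143 and 29.9 TMM-scaled CPM in wild type, 0.309 in the knockdown and 877 in the overexpression. The overexpression exceeded wild type replicate 1 by 6.13 times (95% counting interval 5.63 to 6.68) and replicate 2 by 29.3 times (17.1 to 55.1). The ratio of the knockdown to replicate 1 was 0.00216 (5.47e-05 to 0.0121), and to replicate 2 it was 0.0103 (0.000243 to 0.0689). Neither difference passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p = 0.929 for the knockdown and 0.914 for the overexpression.

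USP31, a deubiquitinase known as the HuR target of interest in this study, was counted at a low level. USP31 (ENSG00000103404; chromosome 16, 23061406 to 23149270, minus strand) had 24 and 3 counts in the wild type replicates, 52 in the knockdown and 0 in the overexpression. The knockdown stood at 16.1 TMM-scaled CPM against 5.22 and 6.90 in wild type, or 3.08 times replicate 1 (1.87 to 5.23) and 2.33 times replicate 2 (0.755 to 11.7). These intervals assume that each count was a separate fragment, which was not checked. With 0 counts in the overexpression, its ratio to wild type replicate 1 had a 95% counting interval from 0 to 0.219, and no fold was taken against the 3 counts of replicate 2. By edgeR, the log2 fold change in the knockdown was 1.41 ± 5.16 (SE; adjusted p = 1), and the adjusted p in the overexpression was 0.861.

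**Figure D3:**
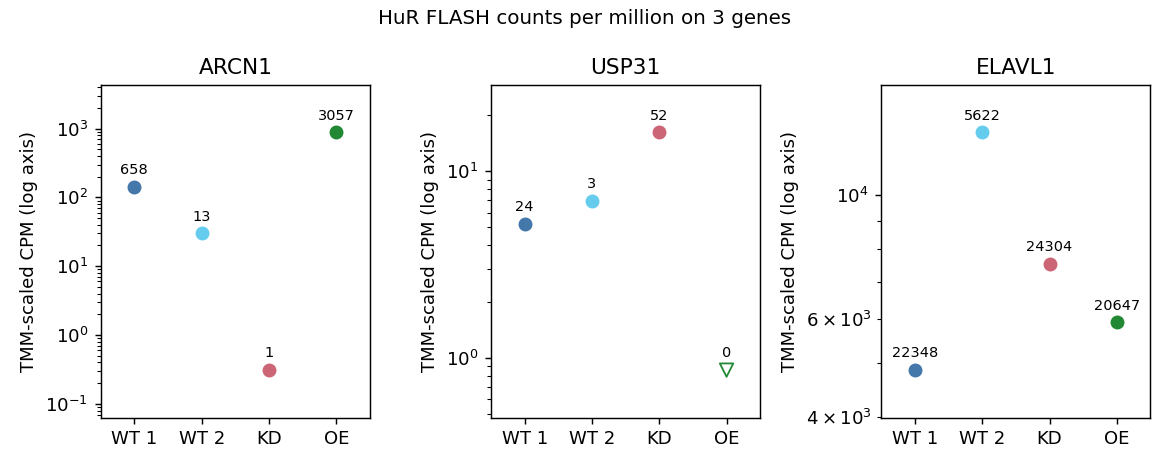
TMM-scaled CPM (vertical log axes, scaled to each gene) of ARCN1, USP31 and ELAVL1 in wild type 1 and 2 (WT), knockdown (KD) and overexpression (OE), 1 point per library, with the raw counts printed above the points. The open triangle is the level of 3 counts for a library with 0, and ARCN1 ran from 1 count in the knockdown to 3057 in the overexpression.

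Knockdown against wild type asked which RNAs were recovered more or less with HuR when circARCN1 was depleted. The 8 genes with the smallest p on the higher side were MRPS25, PRR5-ARHGAP8, ZNF768, EEF1G, HOXD10, RCHY1, MACROD1 and IGF2BP3, all at 0 counts in both wild type libraries. MRPS25, a protein of the mitochondrial ribosome, had 1830 counts in the knockdown, at least 950.2-fold above wild type against a floor of 3 counts over both wild type libraries. IGF2BP3, an RNA-binding protein that stabilises mRNAs, had 1167 counts (at least 606-fold), and the homeobox gene HOXD10 had 1365 (at least 709-fold). On the lower side, DDX6, MEF2A, NETO2, RTL10, MAPKAP1, TALDO1, PPP1R12B and INPP5B all had 0 counts in the knockdown. DDX6 stood at 314 and 6877 TMM-scaled CPM in wild type replicates 1 and 2, and the transcription factor gene MEF2A at 31.7 and 5970. MAPKAP1, a subunit of the kinase complex mTORC2, stood at 44.1 and 4536, and TALDO1, an enzyme of the pentose phosphate pathway, had 55 and 1919 counts.

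None of these 16 genes passed edgeR's test, which called 0 of 9738 genes at an adjusted p below 0.05, with 8 genes at an unadjusted p below that value. DESeq2 called 144 genes, all lower in the knockdown, of which 138 had 0 counts there and which included the 8 lower genes above. Of the 144, 115 also had 0 counts in 1 wild type library, so these calls rested on the other. By limma-voom 0 genes were called, with 982 genes at an unadjusted p below 0.05. Without a test, 3907 genes lay at least 2-fold beyond both wild type libraries, 2767 above and 1140 below. Wild type replicate 1 lay as far beyond the knockdown and the overexpression at 4252 genes, and wild type replicate 2 at 3707. Against wild type replicate 1 alone, 3286 genes were at least 2-fold higher and 4089 lower in the knockdown, so that the side with more genes turned, and against replicate 2 alone there were 4671 and 1927. EEF1G could share reads with its pseudogenes, and PRR5-ARHGAP8 overlaps the 2 genes it joins.

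Among the gene lists, markers of epithelial cells and fibroblasts were lower in the knockdown. Of 10 tested members, 7 lay at least 2-fold below both wild type libraries and 0 above. The median log2 difference was -2.95, or -2.22 with members at 0 set to their bounds, and it was -1.62 against wild type replicate 1 alone and -3.87 against replicate 2. COL1A1, a fibrillar collagen, had 872 and 156 counts in wild type, 0 in the knockdown and 169 in the overexpression. COL1A2 had 359, 51, 10 and 92, and the keratin KRT19 had 8, 11, 0 and 0. COL1A1 and COL1A2 held 872 and 359 of 1489 list counts in wild type replicate 1, and 156 and 51 of 327 in replicate 2. Members could pass the filter through a wild type library alone, so the median and the 7 of 10 were in part set by the filter. The list passed camera at an adjusted p = 0.00505 over 21 lists with the preset correlation. With an estimated correlation camera gave an adjusted p = 0.998. That correlation came out at 1 from 1 residual degree of freedom, so neither setting could be checked. None of its members passed edgeR over all genes, and none passed adjusted over the list alone.

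No other list passed in the knockdown. Macrophage markers had a median of 2.52 log2 units above wild type, with 6 of 10 members at least 2-fold above both wild type libraries (camera adjusted p = 0.0908). At least 10 counts fell on 10 of the 25 listed markers in the knockdown, 2 and 0 in wild type and 1 in the overexpression. Members could pass the filter through the knockdown alone, so the median and the 6 of 10 were in part set by the filter. GPNMB had 25 counts in the knockdown, MARCO 22, VSIG4 20 and the complement gene C1QC 14, each against 0 in both wild type libraries. Mitochondrial transcripts had a median of -0.72, with 11 of 36 members at least 2-fold below both wild type libraries and 1 above (camera adjusted p = 0.0908). With upper-quartile scaling that median was -1.83. MT-CYB had 12511 and 5620 counts in wild type and 1686 in the knockdown, MT-CO3 had 34355, 5955 and 6051, and MT-ND3 had 6107, 1868 and 652. Among 19 members of the p53 and stress response list, 10 lay above both wild type libraries and 4 below. ATF3, a stress-induced transcription factor, had 49 and 0 counts in wild type and 914 in the knockdown, whereas DDIT4 had 759 and 12 against 0.

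Listed HuR targets went both ways in the knockdown, with 9 of 28 at least 2-fold above both wild type libraries and 4 below. Over all 9738 tested genes, 2767 lay above and 1140 below. The splits of HuR targets, deubiquitinases and small noncoding RNAs were close to that of all genes. The cyclin gene CCND1 had 111 and 26 counts in wild type and 1916 in the knockdown, and CCNB1 had 80, 0 and 599. ACTB had 7908 and 4043 against 2460, and CCNA2 had 424 and 8 against 0. Of lipid and cholesterol genes, 8 of 20 lay above and 2 below; the lipoprotein receptor SCARB1 had 933 counts, the sterol synthesis gene HMGCS1 499 and the lipid droplet gene PLIN2 163, each against 0 in both wild type libraries. Of NF-kB pathway genes 6 of 22 lay above and 2 below, with the inhibitor TNFAIP3 at 222 counts and TRAF2 at 107 against 0 in wild type. Deubiquitinases had 10 of 34 above and 3 below, histones 15 of 47 above and 2 below, and ribosomal proteins 11 of 83 above and 7 below. The split was 7 above and 6 below of 19 for lysosome genes, 3 and 3 of 9 for the coatomer, 1 and 5 of 25 for cytoskeleton and adhesion genes, and 3 and 2 of 13 for interferon response genes. It was 3 and 3 of 16 for immediate early genes, 9 and 3 of 41 for RNA-binding proteins, 5 and 2 of 20 for nuclear long noncoding RNAs, and 4 and 2 of 13 for monocyte and cell cycle markers. Inflammatory mediators had 1 of 5 above and 0 below, erythroid and platelet markers 1 and 2 of 3, and small noncoding RNAs 80 and 24 of 290.

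Overexpression against wild type asked the reverse question. The 8 genes with the smallest p on the higher side were FEM1A, IKBKB, RCHY1, TMEM204, MAIP1, MACROD1, IRF2BP1 and LGR4, all at 0 counts in both wild type libraries. IKBKB, a kinase that activates NF-kB, had 1864 counts in the overexpression and 0 in the knockdown, at least 897-fold above wild type against a floor of 3 counts over both wild type libraries. FEM1A, a substrate receptor of a ubiquitin ligase, had 1707 counts (at least 821-fold), and LGR4, a receptor for R-spondins, had 1281 (at least 616-fold). RCHY1 and MACROD1 had 0 counts in wild type, 807 and 853 in the knockdown and 1385 and 1094 in the overexpression. On the lower side, MSL2, PPIL1, CPT1A, NETO2, MAPKAP1, G2E3, YOD1 and ATP5F1D all had 0 counts in the overexpression. MSL2 stood at 54.4 and 7963 TMM-scaled CPM in wild type replicates 1 and 2. PPIL1, a protein of the spliceosome, stood at 70.0 and 6159, and CPT1A, which admits fatty acids to mitochondria, at 2.39 and 5388. NETO2 and MAPKAP1 were at 0 in both modified lines.

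None of these 16 genes passed edgeR's test, which called 0 of 9738 genes, with 10 at an unadjusted p below 0.05. DESeq2 called 184 genes, all lower in the overexpression, of which 182 had 0 counts there and which included the 8 lower genes above. Of the 184, 152 also had 0 counts in 1 wild type library. By limma-voom 0 genes were called, with 1099 at an unadjusted p below 0.05. Without a test, 3756 genes lay at least 2-fold beyond both wild type libraries, 2431 above and 1325 below. Against wild type replicate 1 alone the counts were 2812 higher and 4357 lower, which turned the side with more genes, and against replicate 2 alone 4076 and 2173.

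No gene list passed camera in the overexpression. Splits of lists stand beside 2431 genes above both wild type libraries and 1325 below, over all 9738 tested genes. Listed HuR targets had a median of -1.30 log2 units, with 11 of 28 at least 2-fold below both wild type libraries and 5 above (adjusted p = 0.447). Their median stood at percentile 0.81 among 10000 random lists matched on abundance, and it was -0.67 against wild type replicate 1 and -1.09 against replicate 2, and -2.15 with upper-quartile scaling. CCND1 had 111 and 26 counts in wild type and 0 in the overexpression, the glucose transporter gene SLC2A1 had 169 and 50 against 0, THBS1 had 12 and 50 against 0, and CCNA2 had 424 and 8 against 0. Lysosome and phagocytosis genes had a median of -2.31 (-1.74 with members at 0 set to their bounds), below the central 95% of random lists, with 8 of 19 below and 4 above. That median was -0.58 against wild type replicate 1 alone and -2.96 against replicate 2. The membrane protein gene LAMP2 had 409 and 7 counts in wild type and 0 in the overexpression, and HEXA had 504 and 24 against 0. Mitochondrial transcripts had a median of -0.69 at percentile 0.65, with 10 of 36 below and 1 above, and a median of -1.58 with upper-quartile scaling. MT-ND3 had 6107 and 1868 counts against 195. Coatomer genes had a median of 3.73 at percentile 96.8, with 5 of 9 above and 2 below, and COPZ1 had 4 and 0 counts in wild type against 461. The coatomer median was 1.73 against wild type replicate 1 alone and 4.84 against replicate 2, and ARCN1 itself is a member of the list. COPB2 went the other way, with 406 and 3 counts against 0.

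Small noncoding RNAs had 86 of 290 members above both wild type libraries and 13 below in the overexpression. Their median log2 difference was 0, which stood at percentile 100 among random lists matched on abundance. Random lists with an equal median counted as below it. A difference of 0 is also the value of genes without counts in the libraries compared, so that percentile does not show a shift. SNORA80B had 432 counts there and 834 in the knockdown, against 0 in both wild type libraries. Epithelial and fibroblast markers had a median of -2.09, with 6 of 10 below both wild type libraries and 0 above (camera adjusted p = 0.170). Here too, these markers could pass the filter through a wild type library alone. Immediate early genes had 1 of 16 above and 6 below, with FOS at 37, 29 and 0 counts in wild type replicates 1 and 2 and the overexpression. NF-kB pathway genes had 5 of 22 above and 4 below, with IRAK4 at 1093 counts against 0 in wild type, and CHUK at 0 against 522 and 0. Deubiquitinases had 9 of 34 above and 5 below, lipid and cholesterol genes 6 of 20 above and 4 below, and macrophage markers 3 of 10 above and 0 below. The split was 1 and 2 of 13 for monocyte and cell cycle markers, 3 and 3 of 13 for interferon response genes, 6 and 3 of 19 for p53 and stress genes, and 7 and 6 of 41 for RNA-binding proteins. It was 5 and 2 of 20 for nuclear long noncoding RNAs, 3 and 5 of 25 for cytoskeleton and adhesion genes, 7 and 6 of 83 for ribosomal proteins, and 9 and 2 of 47 for histones. Inflammatory mediators had 1 of 5 above and 1 below, and erythroid and platelet markers 0 of 3 on either side. In both comparisons, 0 members of any list passed edgeR over all genes or adjusted over the list alone.

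**Figure D4:**
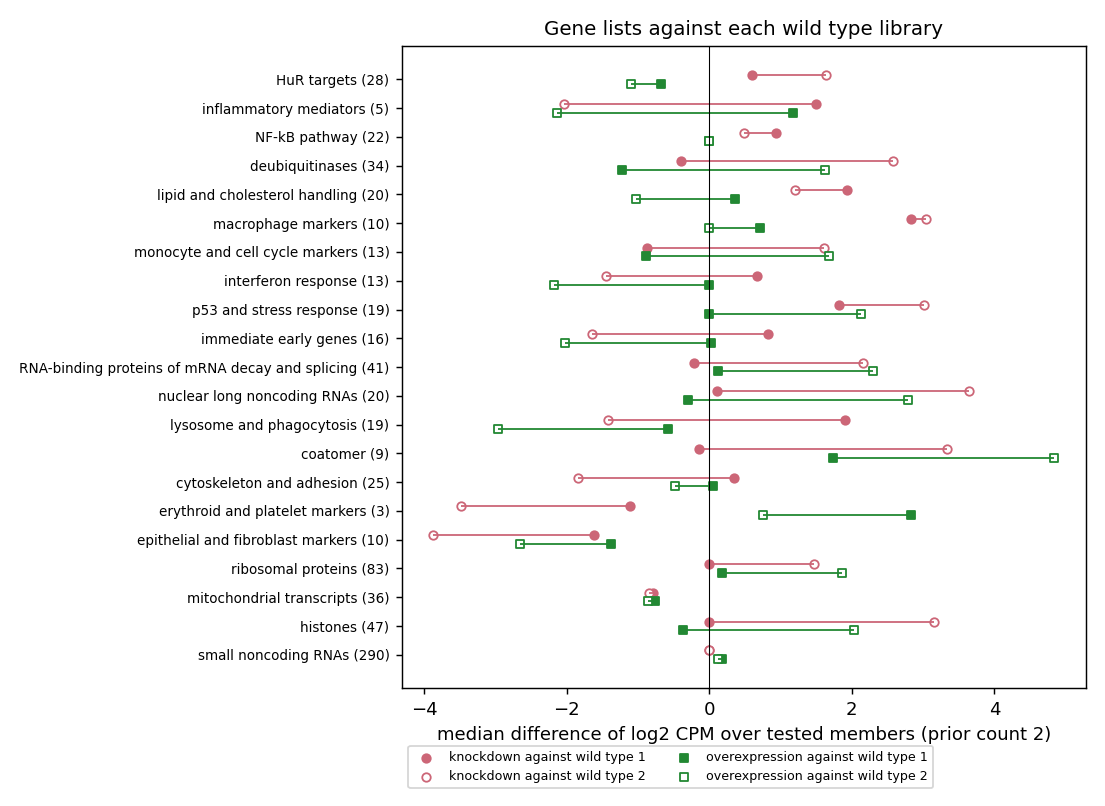
Median difference of log2 CPM (horizontal axis, prior count 2) over the tested members of each gene list (vertical axis, number of members in parentheses) between the knockdown (circles) or the overexpression (squares) and each wild type library; lines join the values against wild type 1 (filled) and wild type 2 (open). Listed HuR targets lay at -0.67 and -1.09 in the overexpression, and mitochondrial transcripts lay below 0 in all 4 comparisons.

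Overexpression was then set against knockdown, to see whether genes went opposite ways. At ARCN1 the overexpression had 3057 counts and the knockdown 1, a ratio of 2833 (508 to 111932), and at USP31 it had 0 against 52, a ratio with an interval from 0 to 0.0681. CCND1 had 1916 counts in the knockdown and 0 in the overexpression, LAMP2 had 1276 and 0, COPB2 had 1092 and 0, and EZR, which links actin to the membrane, had 1018 and 0. In the other direction, the interferon signalling factor STAT2 had 0 and 1107 counts, the nuclear receptor gene PPARG 0 and 856, the deubiquitinase USP24 0 and 567, and the decay helicase UPF1 0 and 290. Listed HuR targets had a median of -1.35 log2 units in the overexpression relative to the knockdown, and no list passed camera (adjusted p = 0.822 for HuR targets). By edgeR, 0 genes passed, and 0 had an unadjusted p below 0.05. DESeq2 called 114 genes, 40 higher and 74 lower in the overexpression, and limma-voom called 0, with 1717 at an unadjusted p below 0.05. This contrast compared 1 library with 1, and its spread was taken from the wild type pair.

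Across genes, log2 differences from wild type in the knockdown and in the overexpression correlated at r = 0.33 with a covariance of 4.10. For comparison, all 4 libraries, wild type ones included, were simulated as unchanged from each gene's mean over the libraries at the common dispersion. The actual wild type libraries were not used. Over 50 simulations the mean r was 0.32 and the covariance 2.62. With the knockdown set against wild type replicate 1 and the overexpression against replicate 2, r was 0.03, and with the replicates exchanged it was 0.05. Genes at least 2-fold beyond both wild type libraries went opposite ways in 284 cases, against a simulated mean of 472. They went the same way in 888 cases above and 733 below, against simulated means of 1054 and 720 and against 691 and 155 for independent lists. On average, the simulated knockdown had 2407 genes above and 1698 below, against 2767 and 1140 observed. The simulated overexpression had 2452 and 1690, against 2431 and 1325 observed. With these unlike totals, the overlaps cannot be set directly against the simulated means. By edgeR 0 genes were called in opposite directions. By DESeq2 it was also 0, and 80 genes were called lower in both, a count for which no value under shared wild type libraries was simulated. Part of any excess may come from the shared wild type libraries, 1 for each comparison being too few for a split with replicates.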

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

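The ranking by the lower replicate, the list medians under other scalings and the marker ratio without the leading gene were chosen after the data were seen, and the other alternatives before. The count of 0 genes past the threshold was the same in all 3 comparisons with RLE or upper-quartile scaling, limma-voom, no filter, the stricter filter, protein-coding genes alone and a one-group dispersion, and in both comparisons with wild type when only the libraries compared were fitted. At the estimated dispersion the main test recovered 0 of 200 simulated changed genes, even those changed 64-fold, so a count that stays at 0 does not show stability. At an unadjusted p below 0.05, upper-quartile scaling gave 281, 251 and 58 genes in the knockdown, the overexpression and their difference, against 8, 10 and 0 with TMM. DESeq2 called 144, 184 and 114 genes, and the cause was not tested.

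Genes beyond both wild type libraries fell to 1264 in the knockdown and 1325 in the overexpression with at least 50 counts in 2 libraries, since 3304 genes remained. With 1 wild type replicate left out, they ranged from 6598 to 7375 and from 6249 to 7169, since 1 library is easier to exceed than 2. Of these genes the stricter filter left 871 above and 393 below in the knockdown, and 840 and 485 in the overexpression. The list called in the knockdown was lost with an estimated correlation (0 lists). With 1 residual degree of freedom that correlation came out at 1 for this list, so the loss decides nothing. The preset 0.01 could not be checked either. Outside the central 95% of random lists lay 3 lists in the knockdown, 4 in the overexpression and 2 in their difference. Small noncoding RNAs were among these each time, with a median of 0 and ties counted as below, so their place shows no shift. The cause of the other shifts was not tested. With upper-quartile scaling, the median of all genes moved from -0.10 to -0.45 in the overexpression. The list median changed sign in the knockdown for HuR targets (0.79 to -0.32), inflammatory mediators, lipid and cholesterol genes, monocyte and cell cycle markers, RNA-binding proteins, lysosome genes and ribosomal proteins, and in the overexpression for p53 and stress genes and ribosomal proteins. The correlation of knockdown with overexpression differences fell to 0.0271 and 0.0458 with a separate wild type replicate for each, which removes the shared controls. Of the 20 most abundant wild type genes, 6 to 17 stayed among the top 20 of 1 replicate, and 8 when genes were ranked by the lower replicate; the cause was not tested.

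Adjusted p-values of named genes crossed 0.05 in 16 cases, all with DESeq2 and on genes at 0 in a modified line. Leaving out a wild type replicate left no residual degree of freedom, so no test was made. No paired analysis was possible because the groups share only 1 replicate number. Depth limited wild type replicate 2 most, with 477 genes at 50 counts or more against 4859 in replicate 1.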

Other observations

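All tests in this part on differences between libraries and on myeloid transcripts were chosen after the result was seen; those on ARCN1 and on 3' untranslated regions were set before theirs were seen, although the test of A content was added once the U content was known.

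Transcripts of RNA-binding proteins of decay and splicing took 1.89% and 1.85% of wild type counts, 1.83% of knockdown counts and 1.77% of overexpression counts over 41 genes. Without ELAVL1 these shares were 1.28%, 0.931%, 1.04% and 1.15%, and no test compared them. Part of the list's counts came from ELAVL1, which is a member, and from HNRNPU. HNRNPU had 6855 and 28 counts in wild type replicates 1 and 2, 4704 in the knockdown and 8305 in the overexpression. The long noncoding RNAs listed under the name nuclear, whose location was not checked, took 0.617%, 0.0950%, 0.751% and 0.634%. MALAT1, a nuclear transcript of speckles, led them with 8889, 172, 14407 and 12559 counts, and NORAD, a decoy of PUMILIO proteins, had 2753, 14, 33 and 907. HNRNPU and MALAT1 were chosen after their values were seen.

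Genes recovered in several libraries carried U-rich 3' untranslated regions. The median U content was 32.6% for 1193 protein-coding genes with at least 50 counts in 3 or 4 libraries, 30.2% for 3160 genes with that many in 1 library, and 28.2% for 8186 genes with no counts. The motif AUUUA occurred at medians of 2.16, 1.85 and 1.15 per kb. With length and abundance held, recurrent genes exceeded the genes of 1 library by 1.91 percentage points (SE 0.273, permutation p = 0.0001, the smallest that 10000 permutations can give). The A content was higher by 1.06 points, or 0.555 of the U difference, between the values set for a general preference for low GC and for U alone. A HuR-like sequence preference among the recurrent genes is a candidate explanation, and a wider preference for low-GC sequence cannot be told apart from it, because no input library shows which transcripts were available.

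The most marked pattern was the difference in gene counts between libraries of any kind. The low depth of wild type replicate 2 would leave the 3 deeper libraries more alike, but their mean correlation differed by -0.02 (-0.0196) from that of pairs with replicate 2. Zeros were most frequent in the shallowest library, but did not follow depth between the other libraries. Among 1348 genes with at least 500 counts in wild type replicate 1, 599 were at 0 in replicate 2, against 226 in the knockdown and 315 in the overexpression. Of the last 2 libraries, the knockdown had the lower total, 3072535 counts against 3349690. The correlations thus argued against low depth as the only cause, and a part for it stays open. circARCN1 genotype alone was argued against as well, since 72.4% of genes differed at least 2-fold between the wild type replicates. Of genes with at least 500 counts in wild type replicate 1, the knockdown or the overexpression, 30.5%, 30.0% and 28.3% had 0 counts in another of these 3 libraries. Amplification of few captured molecules to many counts was neither shown nor excluded by this share, which restates the differences between libraries, and it stays open.

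Few counts fell on transcripts that macrophages make abundantly, although PMA-treated THP-1 cells were the labelled source. A list of 20 abundant myeloid genes held 241 and 76 counts in the wild type replicates, 613 in the knockdown and 134 in the overexpression. CD74 had 104, 27, 129 and 20 of these, the most in every library except the overexpression, where CTSD had 26. IRS4, which is abundant in the HEK293 embryonic kidney line, had 2445, 11, 7638 and 8519, and it prompted a list of 20 markers of that line. Without IRS4, that list exceeded the myeloid list 11.4, 3.26 and 16.3 times in wild type replicate 1, the knockdown and the overexpression, and 0.895 times in wild type replicate 2. With the leading gene of each library also left out (MAP1B in wild type replicate 1, CKB in the knockdown and overexpression, KRT18 in wild type replicate 2), the ratios were 6.58, 1.32, 10.2 and 0.632 in wild type replicate 1, the knockdown, the overexpression and wild type replicate 2. CKB alone held 1192 counts in the knockdown, so the bar of 2 set for all 3 deeper libraries rested there on 1 gene. MAP1B, DSP and CKB led the list in wild type replicate 1, with 1151, 631 and 628 counts; THP-1 cells may make some of these, 2 of its genes (KRT8 and KRT18) are also epithelial markers, and 5 had 0 counts in every library. RNA of another cell line thus stays open, and so does poor HuR binding of myeloid transcripts: 12 inflammatory HuR targets had a median of 0.839 CPM against 76.8 for 26 others, a ratio of 0.0109, which decides nothing while their transcript levels are unknown.

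ARCN1 was below both wild type libraries in the knockdown and above both in the overexpression. Of 1541 protein-coding genes within 4-fold of its abundance, 62 had this order, and 1 (0.0649%), ARCN1 itself, had ratios as extreme on both sides. Whether these reads came from the linear transcript, the circular RNA or the vector was not tested.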
